A study of Gallus gallus with 4 samples.

How the data were processed

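Polyadenylated RNA from conditional Arp6 knockout DT40 cells was labelled with biotin and hybridised to the Affymetrix GeneChip Chicken Genome Array, 1 array for each of days 0, 2, 4 and 6, per the labels' protocols. Arp6 loss was induced with tetracycline at 2 ug/ml, which shuts off the transgene, and the day 0 culture had none, per the labels. Every array after day 0 therefore differs from it in Arp6, in tetracycline and in time in culture, as no array without tetracycline was taken after day 0. The values deposited by the authors are 1 intensity per probe set and array on a linear scale, made with GeneChip Operating Software according to the series' design text. The signal algorithm and any scaling between arrays are not given in the sources used here, and the medians of the 4 deposited columns, 31.2, 25.6, 31.9 and 28.2, show no common target.

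From these intensities the following was computed. Of 38535 probe sets, 96 controls were left out. Probe sets were kept where the mean log2 value over the 4 arrays was at or above the median of all values, a signal of 29.1, which kept 16658. Each array was shifted to the same median over the kept probe sets, by factors of 0.859, 0.962, 1.02 and 1.19 for days 0, 2, 4 and 6. Signals below the 40th percentile of all scaled values, 19.4, were set to that floor before taking ratios. A ratio whose dimmer signal lay below the array's background, the 95th percentile of its unspiked controls (25.4, 24.9, 32.1 and 45.9 after scaling at days 0, 2, 4 and 6), is given as a lower bound against that level ("at least"), a rule chosen after seeing the data. Ranks, counts, medians and log2 ratios use the floored signals unless a bound is stated. The median log2 ratio of all tested genes was -0.01, 0.0033 and -0.0091 at days 2, 4 and 6 with this scaling. In the deposited values it was -0.17, -0.24 and -0.48 at days 2, 4 and 6, and after scaling to the spike-in controls -0.10, 0.37 and 0.21. All ratios here are relative to the median gene, so a shift common to most genes would not be seen.

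Probe sets were named from the platform annotation given with the series. Of the probe sets other than controls, 27168 had 1 gene symbol, 177 had several and were not named, and 11094 were not listed, which leaves them unnamed here. For a gene with several kept probe sets the one with the highest mean was used, giving 8026 genes. Chromosomes and gene lengths came from the RefSeq table of assembly GRCg7b, which held 8024 of these symbols and placed 8009 on a chromosome. No coordinates are given here.

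With 1 array per day there is no test between days. Genes were counted as higher or lower at a 2-fold difference. For a list of genes, the median log2 ratio was set among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these arrays and is no p-value. The random range leaves out 2.5% of these lists at each end. Lists with fewer than 5 tested genes are given as single values. The trend over days was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, Benjamini-Hochberg adjustment over all tested genes). Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Bootstrap errors of medians come from 500 draws over genes and hold no error between arrays. The 24 lists, the tests and the rule for naming genes were fixed before the data were examined, and 5 further lists, used in the closing section, were written after the main values had been seen.

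Genes were named by this rule, from probe sets with 1 symbol and leaving out clone-like or locus symbols: every Arp6 probe set; the 10 largest mean ratios in each direction among genes different at all 3 later days; the 5 highest and 5 lowest ratios of each day; the 3 members of each list with the largest absolute mean ratio, and any member of the SRCAP list that differed 2-fold; and the 5 lowest trend p-values in each direction among genes 2-fold different between days 0 and 6; and every chromosome outside the random range at all 3 days. Other list members named beside them were chosen after their values were seen.

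Both statistical steps were tested on simulated data. With 50 genes at each size of change among 8026, the trend step at an adjusted p under 0.05 recovered 0, 18, 25 and 32 of them for log2 changes of 1, 2, 3 and 4 from day 0 to day 6, with 7 false calls. Of 200 simulated lists of 30 genes with no shift, 9 lay outside the random range, and with a log2 shift of 0.5, 194 did.

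Alternatives were other scalings (none, quantile, 75th percentile), other filters on dim probe sets (none, 75th percentile), other floors (none, 60th percentile, or a pseudocount of 29.1 in place of a floor), the mean of a gene's probe sets, every probe set by itself, 3-fold and 1.5-fold thresholds, trends without each day, on log2(day + 1) or with limma-trend, and other bounds between chromosome classes. Scaling to the 27 spike-in control probe sets, a floor at the highest unspiked control (73.3 after scaling) and matching of list members through RefSeq synonyms were added after seeing the data.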

Results

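Gene expression was measured in chicken DT40 cells, a B cell lymphoma line, in which the gene for the nuclear actin-related protein Arp6 (symbol ACTR6) had been disrupted and Arp6 was supplied by a transgene that tetracycline shuts off. Arp6 is a subunit of the SRCAP complex, which places the histone variant H2A.Z into chromatin. The 4 arrays were taken before tetracycline (day 0, Arp6 on) and after 2, 4 and 6 days in tetracycline at 2 ug/ml (Arp6 off), with 1 array per day and no replicates, so each ratio compares 2 arrays and carries no replicate error. The title of the study concerns Arp6 and where chromosome territories lie within the nucleus, and the arrays ask which genes differ in level once Arp6 is lost. Each array gave signals for 38439 probe sets other than controls, and 8026 genes were bright enough to be tested. A gene was counted as higher or lower when its signal differed at least 2-fold from day 0, and the number of arrays limits the precision of every value.

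The targeted gene followed the labels on all 4 arrays. The ACTR6 probe set with the higher mean signal read 8148 at day 0 and 331, 325 and 322 at days 2, 4 and 6 as deposited, which after scaling was 22.0-fold, 21.1-fold and 18.3-fold lower than at day 0. A different ACTR6 probe set read 8247 at day 0 and 4.49, 29.1 and 7.06 afterwards. With its signals below background (the 95th percentile of the array's unspiked controls) at all 3 later days, it was at least 285-fold, 220-fold and 154-fold lower. Where either probe set lies relative to the deleted exons or the transgene is unknown here.

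**Figure D1:**
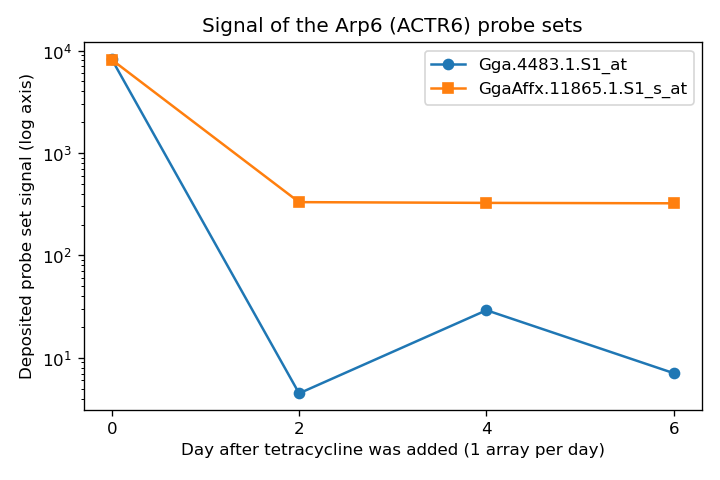
Deposited signal (log axis) of both ACTR6 probe sets against the day after tetracycline was added, with 1 point per array. Both probe sets fall between day 0 (8148 and 8247) and day 2 (331 and 4.49).

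At day 2 the genes furthest above day 0 included NTNG2 (netrin-G2, a membrane-anchored netrin), 4.36-fold higher, and PACS2, 4.20-fold higher. TSC2, a regulator of mTOR signalling, CX3CR1, a chemokine receptor, and BCKDHA, a subunit of the enzyme that breaks down branched-chain keto acids, were below background at day 0 and at least 3.75-fold, 4.32-fold and 3.19-fold higher at day 2. Below day 0 after ACTR6 came PSMB5, a catalytic subunit of the proteasome, TBX1, SSTR3 and SLC30A2, all below background at day 2 and at least 3.90-fold, 3.53-fold, 3.35-fold and 3.33-fold lower. At days 4 and 6 PSMB5 stood at log2 ratios of -0.04 and -0.50, and its second probe set at -0.70, -0.45 and -1.67 at the 3 later days, the last with a signal below background. TBX1 stood at 0.53 and 0.23 at days 4 and 6, while TSC2 was below background at day 4 and at least 3.99-fold higher at day 6. In all, 194 genes were higher and 238 lower at day 2, which is 2.42% and 2.97% of the genes tested. A second probe set of PACS2 gave log2 ratios of -1.34, 0.39 and -0.67 at the 3 later days, against 2.07, 2.18 and 1.62 for the probe set used.

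At day 4 the extracellular matrix proteoglycan gene LUM (lumican) was 9.26-fold higher, CSTA (cystatin A, a cysteine protease inhibitor) 7.88-fold and NTNG2 6.81-fold. PLCG1, a phospholipase of receptor signalling, and WIPF2 were below background at day 0 and at least 6.58-fold and 4.98-fold higher, and a second probe set of PLCG1 stood at 2.07, 2.08 and 0.98 on the log2 scale at the 3 later days. ACTR6 was followed at the lower end by HVCN1, a proton channel of B cells and phagocytes, below background and at least 8.92-fold lower, and SPI1, the transcription factor PU.1, 7.72-fold lower. The elongation factor gene SUPT6H and the RNA sensor gene TLR7 were below background and at least 5.10-fold and 4.60-fold lower, and SUPT6H was back at a log2 ratio of -0.67 at day 6. At day 4, 463 genes were higher and 411 lower.

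At day 6 LUM was 28.7-fold higher, with a signal of 1069 against 37.2 at day 0. MAT1A, an S-adenosylmethionine synthetase, was 18.7-fold higher, HPGDS (hematopoietic prostaglandin D synthase) 14.1-fold (a log2 ratio of 3.81, and 5.02 by its second probe set), OSTN (osteocrin) 11.9-fold and GPT2, the mitochondrial alanine aminotransferase, 11.2-fold. CD74, the invariant chain of MHC class II, was 32.3-fold lower, with a signal of 3110 at day 0 and 96.3 at day 6. PINLYP, SPI1 and WDFY4, a gene of antigen presentation, were below background and at least 7.82-fold, 9.53-fold and 9.49-fold lower, and ACTR6 was 18.3-fold lower by the probe set used. In all, 681 genes were higher and 670 lower at day 6. The split into higher and lower depended on how the arrays were scaled. With the deposited values as they stand, 147 genes were higher and 403 lower at day 2, 286 and 740 at day 4, and 263 and 1603 at day 6, while scaling to the spike-in controls, chosen after seeing the data, gave 152 and 298, 1016 and 198, and 985 and 471.

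At all 3 later days 89 genes were higher than day 0 and 33 were lower, against 51 and 111 with the deposited values unscaled. By mean ratio LUM, NTNG2, MAT1A, GPT2, OSTN, BCKDHA, CTXN1, STC2, CHAC1 and IDH1 led the genes that were higher. Among them STC2 (stanniocalcin-2), CHAC1, which degrades glutathione, and GPT2 belong to the list of ATF4 and amino acid response genes. IDH1, the cytosolic isocitrate dehydrogenase, was 2.26-fold, 6.12-fold and 7.43-fold higher at days 2, 4 and 6, and CTXN1, below background at day 0, was at least 2.96-fold, 4.55-fold and 4.45-fold higher. Of the 89 genes that were higher 36, and of the 33 that were lower 24, had a dimmer signal below background in at least 1 ratio, and with bounds in place of those ratios 69 and 25 were still 2-fold different at all 3 days. The genes that were lower were led by ACTR6, SPI1, GPR157, WDFY4, FAM110D, BCL6, VAT1, RAB9B, KCNA2 and TMED8. BCL6, a transcriptional repressor of germinal centre B cells, was 2.26-fold and 5.26-fold lower at days 2 and 4 and, below background, at least 5.28-fold lower at day 6, and GPR157 was 2.39-fold, 7.04-fold and at least 5.35-fold lower. Their second probe sets stood at -0.49 and -1.41 on the log2 scale at days 2 and 4 for BCL6, and at -0.69 and -1.19 for GPR157. Of these genes, 23 that were higher and 17 that were lower had a second probe set, which went the same way on all 3 days for 11 and 11 of them and was itself 2-fold different on all 3 days for 5 and 4. VAT1 stood at -1.26 and -1.21 on the log2 scale at days 2 and 4 and was at least 7.44-fold lower at day 6, below background, while its second probe set gave -0.43, -1.08 and 0.03, and TMED8 stood at -1.42, -1.92 and -2.53 against -0.84, -0.32 and -0.99.

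A count of this kind also arises when 1 array stands apart from the other 3, whatever its label. With day 2 in the place of day 0 the other 3 arrays were all higher for 48 genes and all lower for 0. The counts were 76 and 53 with day 4 and 238 and 102 with day 6 in that place, against 89 and 33 for day 0. Shuffling the 4 values within each gene 100 times gave means of 111 and 47.6, and the 89 and 33 genes were not above them. The shuffle means follow from averaging the counts above over the 4 arrays, so they are no separate test. They also keep the distance of day 6 from the other arrays. The comparison therefore cannot tell whether the day 0 counts exceed those of unchanged arrays.

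The ATF4 and amino acid response list, genes that cells raise when amino acids run short or the integrated stress response is active, stood furthest above day 0 of all lists at days 2 and 6, and second to the 6 fibroblast and endothelial genes at day 4. Its median log2 ratio over 27 tested genes was 0.58 at day 2, 0.74 at day 4 and 1.10 at day 6, and 0 of 10000 random lists matched on mean expression reached it on any day. The number of its members at least 2-fold higher was 5, 10 and 15 at the 3 days, and 0 were 2-fold lower. GPT2 was 3.66-fold, 6.52-fold and 11.2-fold higher, CHAC1 3.15-fold, 3.33-fold and 10.7-fold, and STC2, below background at day 0, at least 2.77-fold, 2.99-fold and 7.00-fold. A second probe set of STC2 gave log2 ratios of 0.39, 0.56 and 2.06. The cystine transporter gene SLC7A11 was 3.84-fold, 5.20-fold and 4.36-fold higher (log2 ratios of 0.12, 0.77 and 0.73 by its second probe set), the serine synthesis gene PSPH 2.55-fold, 2.73-fold and 3.67-fold, and PSAT1, of the same pathway, 1.79-fold, 2.78-fold and 3.39-fold. Members near day 0 throughout included LARS, AARS1 and NARS, aminoacyl-tRNA synthetases with day 6 log2 ratios of -0.03, 0.01 and 0.15. Lists for the neighbouring stress pathways stood nearer to day 0. The unfolded protein and heat shock response list (32 genes) had medians of 0.04, -0.02 and 0.16 (-0.31 at day 6 with the deposited values unscaled), inside its random range on each day, the range that leaves out 2.5% of random lists at each end, although its 17 endoplasmic reticulum chaperones, taken alone after seeing the data, lay below that range at day 4 (-0.19) and above it at day 6 (0.28), with HERPUD1, of protein degradation at the endoplasmic reticulum, 2.92-fold higher at day 6, SDF2L1 2.55-fold higher and the chaperone gene HSPH1 at -1.17 on the log2 scale.

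The B cell identity and antigen receptor list stood furthest below day 0 of all lists at days 4 and 6. At day 2 the interferon list and the macrophage and granulocyte list, with fewer genes, lay lower. Its median over 27 genes was -0.47 at day 2, -0.67 at day 4 and -1.18 at day 6, and 0 of 10000 matched random lists lay as low on any day. The number of its members at least 2-fold lower was 4, 9 and 15, and 1 member, PRDM1, a transcription factor of plasma cells, was 2-fold higher, at day 6 (2.87-fold). SPI1 was 2.24-fold, 7.72-fold and, below background at day 6, at least 9.53-fold lower, CD74 1.61-fold, 4.72-fold and 32.3-fold, and the B cell surface gene CD72 1.90-fold, 6.32-fold and 12.1-fold (2.83-fold at day 4 and at least 3.99-fold at day 6 by its second probe set). The Bruton kinase gene BTK was 16.4-fold lower at day 6, CD79B, a signalling chain of the antigen receptor, 5.54-fold, and IRF8 4.94-fold. Other B lineage genes stayed near day 0, with day 6 log2 ratios of 0.16 for IRF4, 0.43 for XBP1, 0.13 for JCHAIN (the immunoglobulin J chain), -0.17 for POU2AF1 and 0.30 for PLCG2. The directions of this list and of the ATF4 list were the same under the 4 other scalings at all 3 days.

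**Figure D2:**
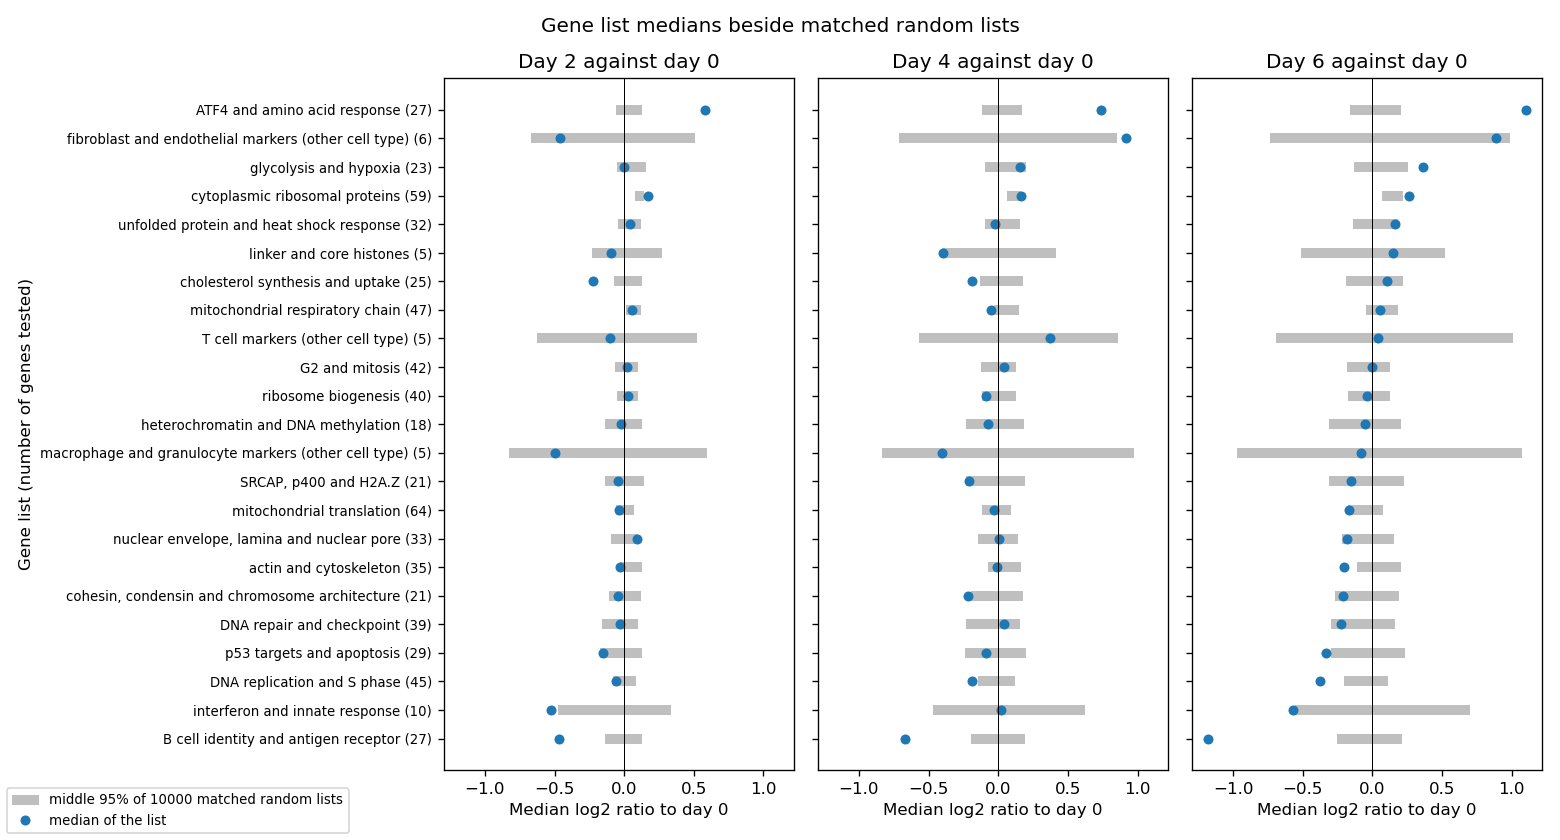
Median log2 ratio to day 0 of each list of genes fixed in advance (points) at days 2, 4 and 6, with the number of genes tested in brackets, and the random range of 10000 lists matched on mean expression, less 2.5% at each end (bars). At day 6 the ATF4 list stands at 1.10 and the B cell list at -1.18, both outside their bars.

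**Figure D3:**
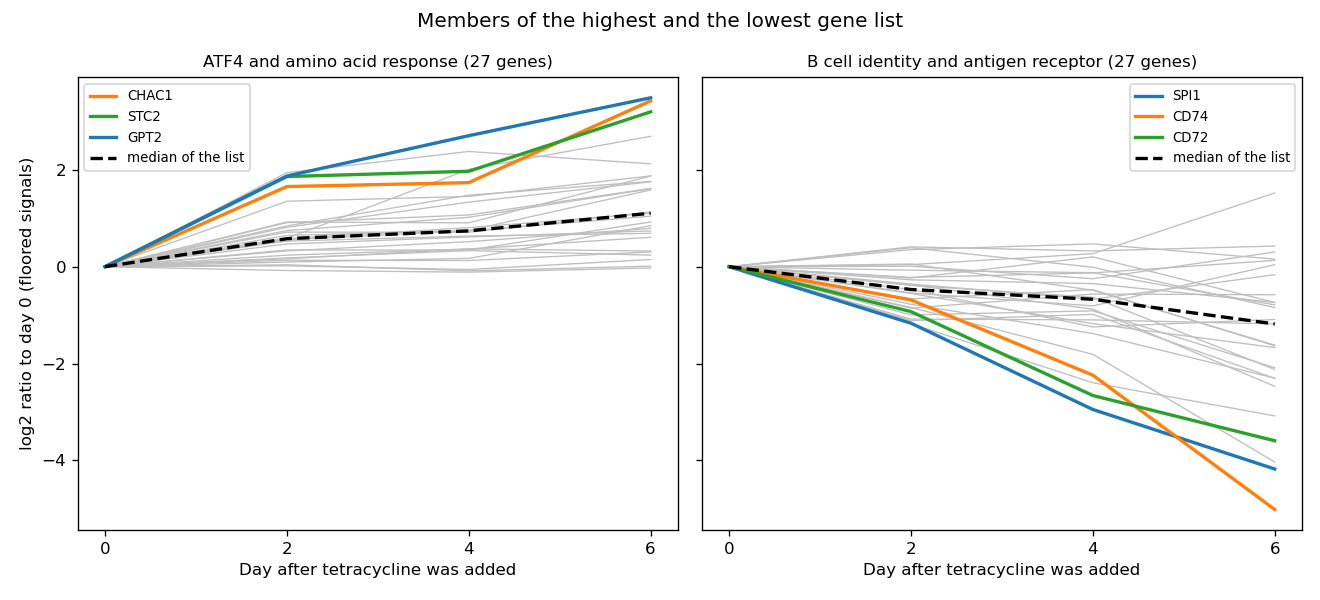
Log2 ratio to day 0 of every tested member of the ATF4 and B cell lists against the day, with 27 genes in each panel, 3 named genes in colour and the list's median dashed. By day 6 CD74 reaches -5.01 and GPT2 3.49.

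Genes of DNA replication and S phase (45) had medians of -0.06, -0.19 (0.17 with spike-in scaling) and -0.37 at days 2, 4 and 6, and 0 of 10000 matched random lists lay as low at day 6. The origin recognition gene ORC1 was 4.01-fold lower at day 6, the primase gene PRIM1 2.54-fold and the helicase gene MCM5 2.08-fold, while CCNE1 (cyclin E) was at 0.83, 1.17 and 0.57 on the log2 scale. The dim gene PRIM2 stood at -0.85 at day 2 and was below background at days 4 and 6. G2 and mitosis genes (42) had medians of 0.02, 0.04 and -0.0031, with CENPK at -1.84 at day 6, and the sign of each median turned under at least 1 other scaling. CENPN stood at 0.38, 0.62 and 0.66 at the 3 later days (0.19, 0.38 and 0.19 by its second probe set). CENPO stood at -0.67, -0.66 and -0.50, against 0.45, 0.02 and 0.25 by its second probe set. DNA repair and checkpoint genes (39) had medians of -0.03 and 0.04, whose signs turned with quantile normalization (0.04 and -0.0090), and -0.22, with RAD50 at -1.42, XRCC5 at -1.32 (-0.22 by its second probe set) and ATR at -0.98 at day 6, and none of the 3 medians lay outside the random lists' range.

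The p53 target and apoptosis list (29 genes) had medians of -0.15, -0.09 (0.27 with spike-in scaling) and -0.33, and 140 of 10000 random lists lay as low at day 6. BCL2, which protects cells from apoptosis, was 5.39-fold higher at day 6 (2.12-fold by its second probe set), while BTG2 and TP53INP1 stood at -1.26 and -1.39. Cholesterol synthesis genes (25) had medians of -0.23 at day 2 and -0.19 at day 4, when 0 and 52 of 10000 random lists lay as low, and 0.11 at day 6 (-0.36 with the deposited values unscaled). FDPS and LSS, enzymes of that pathway, stood at -0.77 and -0.60 at day 2 and both at -0.11 at day 6 (0.21 by the second probe set of LSS), and the day 4 median turned to 0.17 with spike-in scaling. HSD17B7, of the same list, stood at 0.08, 0.34 and 0.76 at the 3 later days (-0.42, -0.01 and 0.55 by its second probe set). Glycolysis and hypoxia genes (23) had medians of 0.16 at day 4 and 0.37 at day 6, when 9 of 10000 random lists reached as high, with HK2 at least 3.19-fold and PFKFB3 2.91-fold higher. At day 6, 17 of these genes were above day 0 and 6 below it. BNIP3L and HK1 were among the lower ones, at -1.02 and -0.52 (-0.15 by the second probe set of HK1). With the deposited values unscaled the list's medians at days 4 and 6 were -0.09 and -0.10. Cytoplasmic ribosomal protein genes (59) had medians of 0.17, 0.17 and 0.26, led by mean ratio over the 3 days by RPS6 (0.36), RPS3 (0.33) and RPL9 (0.33), above the random range each day, but the sign turned at days 4 and 6 with unscaled values (-0.08 and -0.20) and at day 6 with quantile normalization, and 0 of the 59 genes differed 2-fold.

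Actin and cytoskeleton genes (35) had medians of -0.03 (below the random range, but 0.0302 without the filter on dim probe sets), -0.01 and -0.20, which at days 4 and 6 turned to 0.36 and 0.02 with spike-in scaling, and 9 of 10000 random lists lay as low as the day 6 median. ARPC1B was at -1.26, while the dim adhesion gene VCL was at 1.80 and the filamin gene FLNA, below background at day 0, at 1.59 or more. Cohesin, condensin and chromosome architecture genes (21) had medians of -0.04, -0.21 and -0.21, below the random range at day 4 (0.15 with spike-in scaling, and 0.02 at day 6), with the cohesin gene SMC3 at -1.14 that day, STAG1 at -0.63 (0.37 by its second probe set) and the condensin gene NCAPG at -0.67 (-0.26 by its second probe set). Mitochondrial respiratory chain genes (47) had medians of 0.06, -0.05 and 0.06, the day 4 value below the random range but 0.31 with spike-in scaling, and the day 2 and day 6 values at -0.10 and -0.41 with the deposited values unscaled. Their largest mean ratios were those of ATP5E, COX5A and NDUFA1, at -0.54, -1.04 and -0.90 at day 6, with COX5A at -0.06 by its second probe set. The interferon and innate response list had 10 tested genes and medians of -0.53, 0.02 (-0.23 with the deposited values unscaled) and -0.57, with IRF7 at -0.52 and BF2 below background at day 6.

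Several lists stayed inside their random range at all 3 days, and each of them had a median whose sign turned under another scaling. Leaving the arrays unscaled or scaling to the spike-in controls moves all genes of an array by the same amount, so a turn under either says little about the list itself. The SRCAP, p400 and H2A.Z list (21 genes) had medians of -0.04, -0.21 and -0.16. Apart from ACTR6, MRGBP, a subunit of the NuA4 acetyltransferase, was the 1 member to differ 2-fold, 2.22-fold lower at day 6. EPC1 stood at 0.77, 0.51 and 0.51 at the 3 later days. The H2A.Z genes H2AFZ and H2AZ2 stood at -0.10 and -0.20 at day 6. Heterochromatin and DNA methylation genes (18) had medians of -0.02, -0.07 and -0.05, with CBX1, which encodes HP1 beta, at -1.31 at day 4 but at 0.35 by its second probe set, EHMT1 at -0.99 and DNMT3A at 0.99. Nuclear envelope, lamina and nuclear pore genes (33) had medians of 0.09, 0.01 and -0.18, with LEMD2 at -0.91 at day 6 (0.05 by its second probe set) and dim signals for LMNA and SYNE1. Ribosome biogenesis genes (40) had medians of 0.03, -0.09 and -0.04, with POLR1B, MYBBP1A and BYSL furthest from day 0 by mean ratio. Mitochondrial translation genes (64) had medians of -0.04, -0.03 and -0.17, with MRPL1 at 2.12 and MRPL46 at -0.63 at day 6. MRPL21, with the largest mean ratio of that list, was below background at day 0 (19.8 after scaling) and read 47.0, 82.3 and 52.1 afterwards. Linker and core histones (5 genes) had medians of -0.09, -0.39 and 0.15, with the macroH2A gene H2AFY2 at least 2.46-fold lower at day 6, H3F3C at -0.79 and the linker histone gene HIST1H111L 2.31-fold higher.

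Markers of other cell types were mostly dim. The T cell list (5 tested genes) had medians of -0.10, 0.37 and 0.04 and held the bright gene CD3D, at 2382 at day 0 and 911 at day 6, with CD247 at -1.56 and CD8A dim. The macrophage and granulocyte list (5 genes) had medians of -0.50, -0.41 and -0.08, with TLR2A at least 2.13-fold lower and CSF1R at 1.13 on the log2 scale at day 6 and C1QA dim. The fibroblast and endothelial list (6 genes) had medians of -0.46, 0.92 and 0.89. It was above its random range at day 4, and beside LUM its members FN1 and COL6A2 reached signals of 89.4 and 70.4 at day 6, close to the highest unspiked control after scaling, 73.3, and a second COL6A2 probe set stood at -0.50. Of erythroid markers 3 genes were tested, TFRC near day 0 at 0.18, and HBAD and TAL1 dim. Of the 23 lists with a median, 2, 3 and 3 lay above the random range at days 2, 4 and 6, and 4, 5 and 5 below it, out of 69 medians.

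Over the 4 days, genes were ranked by limma's p for a straight line, which weighs the slope against the departure from it. LUM, MBNL2, MAT1A, MSLN and PPP3CA, a catalytic subunit of calcineurin, led those that ended at least 2-fold higher. SPI1, GPR157, CD72, CCNA1 (cyclin A1) and AMY2A led those that ended at least 2-fold lower. MBNL2, a splicing regulator, was 7.69-fold higher at day 6, PPP3CA 7.87-fold and MSLN at least 5.33-fold, while CCNA1 and AMY2A, below background at day 6, were at least 3.96-fold and 7.71-fold lower. A second probe set of AMY2A stood at -0.51, -0.58 and 0.10. In limma's linear model of log2 signal on day, 0 genes had an adjusted p under 0.05, the lowest being 0.160, and 1480 had an unadjusted p under 0.05, of which 727 had a rising slope. With the deposited values unscaled 248 of 2334 such genes had a rising slope, and with no filter on dim probe sets 338 of 1866. With 2 residual degrees of freedom the error is the departure from a straight line. Without day 0 the unadjusted count was 765, and without day 2 it was 935. Keeping only brighter probe sets gave 146 genes at the adjusted threshold, and letting limma's prior variance follow the signal gave 604. The real order of the arrays gave more genes at the unadjusted threshold than any of the other 11 orders, of which the highest gave 755, and 579 genes with a steady course and a 2-fold end difference against 256 at most, but 12 orders are too few for a share under 0.05.

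Array pairs lay further apart the more days separated them from day 0. The SD of the log2 difference over genes was 0.47 between days 0 and 2, 0.64 between days 0 and 4 and 0.80 between days 0 and 6, with 432, 874 and 1351 genes at least 2-fold apart. Between days 2 and 4 it was 0.54, between days 2 and 6 0.69 and between days 4 and 6 0.64. Ratios that share day 0 correlate across genes without any effect. Pearson's r across genes was 0.563 for days 2 and 4, 0.515 for days 2 and 6 and 0.626 for days 4 and 6, beside means of 0.500, 0.499 and 0.500 in the shuffles, and genes are not independent replicates. The covariances were 0.171, 0.195 and 0.320 beside 0.204, 0.203 and 0.204 in the shuffles. Days 4 and 6 shared 277 higher and 183 lower genes, beside means of 188 and 116 in the shuffles, and 39.3 and 34.3 for independent lists. Days 2 and 4 shared 115 and 71, and days 2 and 6 137 and 71, all below the shuffles' means of 187 and 117 and of 186 and 117, though above the 11.2 and 12.2 and the 16.5 and 19.9 of independent lists, which leave out the shared day 0 array. The shuffles mix the distance of day 6 from the other arrays into every pair, so they do not stand for unchanged arrays. The day 2 minus day 0 and day 6 minus day 4 differences, which share no array, correlated at 0.0778 across genes.

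Genes on microchromosomes, the small gene-rich chromosomes of birds, stood slightly lower than genes on macrochromosomes. The difference in median log2 ratio between 2919 genes on chromosomes 11 and above and 3802 on chromosomes 1 to 5 and Z was -0.03 at day 2 (-0.05 to -0.02 in bootstrap draws over genes, less 2.5% at each end), -0.06 at day 4 (-0.09 to -0.03) and -0.05 at day 6 (-0.08 to -0.02). The microchromosome median itself was -0.03, -0.03 and -0.04, and 5, 0 and 2 of 10000 matched random lists lay as low. Genes on chromosomes 6 to 10 had medians between -0.01 and 0.01. Of the 29 chromosomes with at least 30 tested genes, Z (337 genes) was above the random range at all 3 days, with medians of 0.04, 0.08 and 0.09, and chromosome 26 (124 genes) below it, with -0.10, -0.09 and -0.14. All these ratios share the day 0 array, so the 3 days are not separate observations. A day 0 array that stood apart would move a class or chromosome the same way on every day. With no filter on dim probe sets the difference between the classes was 0.0016 at day 2, -0.09 at day 4 and -0.11 at day 6.

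**Figure D4:**
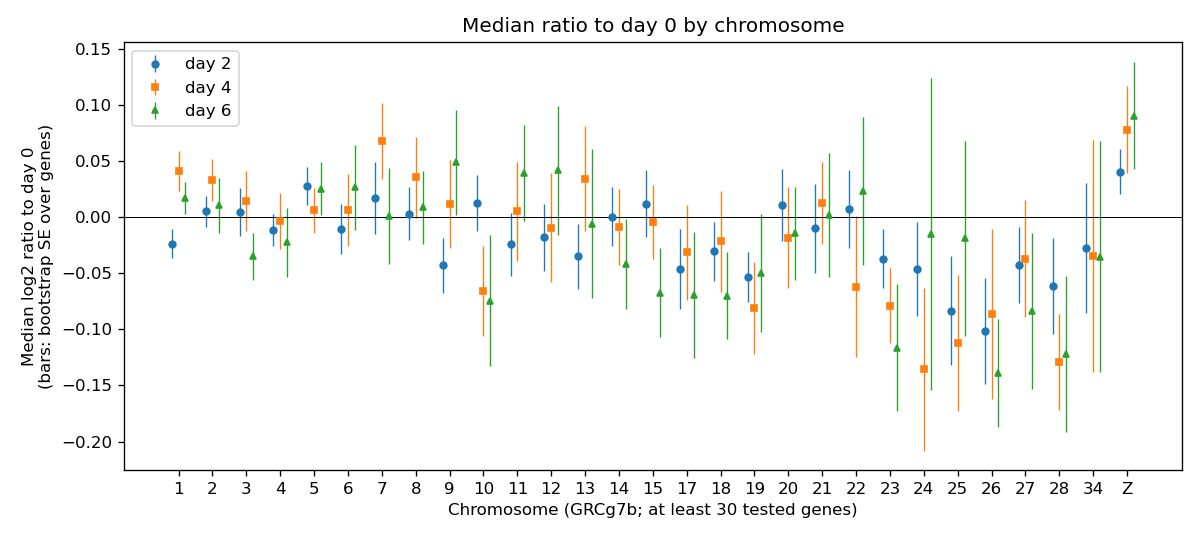
Median log2 ratio to day 0 of the tested genes of each chromosome at days 2, 4 and 6, with bars for the bootstrap SE over genes. Chromosome Z stands at 0.04, 0.08 and 0.09 and chromosome 26 at -0.10, -0.09 and -0.14.

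The controls on the arrays differed between days. The spike-in controls averaged 0.953, 0.656 and 0.619 times their day 0 signal at days 2, 4 and 6, and the trimmed mean of all other probe sets 0.882, 0.849 and 0.728 times. The ratio of the 3' to the 5' probe set, a sign of RNA integrity, ranged from 1.65 to 2.22 for actin and from 0.872 to 0.937 for GAPDH, with day 6 at 2.22 and 0.880. For 3577 genes with more than 1 kept probe set, the first and second one correlated across genes at 0.246 at day 2, 0.375 at day 4 and 0.500 at day 6, and genes are not independent replicates. Of genes 2-fold different by the first probe set, the second went the same way for 75.2%, 73.7% and 81.8% and was itself 2-fold different for 18.1%, 34.1% and 42.4%. Among named genes with a mean ratio of 2-fold or more and a second probe set, 17 of 18 had the same direction in both, the exception being PACS2.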

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

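The patterns weighed here were picked after they had been seen, while the scalings they were set against, other than that to the spike-in controls, were fixed before the data were examined. Tests of scaling for the ATF4 list, endoplasmic reticulum stress, tetracycline, a lower share of B cells and gene length at days 2 and 4 were chosen only after the result was seen. The values of the chromosome tests at day 6 and of the plasma cell test had not been seen, the latter because PRDM1, JCHAIN, XBP1 and IRF4, already seen, were left out of its list.

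Kept probe sets without a single gene symbol took no part in the gene comparisons, and 49 of them were at least 2-fold higher than day 0 at all 3 later days. A further 23 were at least 2-fold lower at all 3 later days. Of these, 33 and 23 passed the highest unspiked control on at least 1 array.

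The ATF4 and amino acid response list stood above day 0 from day 2 on. The tables argue against scaling, since the lowest day 6 median under the 4 other scalings was 0.64. Endoplasmic reticulum stress as the whole cause would need chaperone genes to follow, but the list's median exceeded the chaperones' median plus their interquartile half-range by at least 0.43 on every day, although the chaperones' median did reach 0.28 at day 6. From day 4 to day 6 the median change was 0.50 for the chaperones and 0.30 for the ATF4 list. Endoplasmic reticulum stress as a part of the cause therefore stays open. Tetracycline, which can also inhibit mitochondrial translation, cannot be told apart from loss of Arp6, because every array with the list higher, starting with a median of 0.58 at day 2, had both. Time in culture is confounded in the same way, as no array without tetracycline was taken after day 0. Loss of Arp6 therefore stays open as a hypothesis beside the drug and the time in culture.

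The B cell list stood below day 0 from day 2 on. A lower share of B cells alone would lower all abundant B cell genes alike, if other cells lacked them. Among 9 such genes with a day 0 signal over 1000 the fall was uneven. The upper quartile of the day 6 log2 ratio was 0.13 and the lower quartile -2.47. With 9 genes the quartiles rest on few of them, and the upper quartile and the highest ratio equal the values of JCHAIN (0.13) and XBP1 (0.43). A lower share as part of the cause therefore stays open. A move towards a plasma cell state may account for part of the list's fall. The 36 plasma cell and secretory genes had a day 6 median of 0.31 at the 99.97th percentile of random lists. Only 1 of them was 2-fold higher, beside 8.48% of all tested genes, and the list was not run under the other scalings. It also holds secretory genes, so it cannot tell a plasma cell state from the endoplasmic reticulum stress left open above. On the B cell list the plasma cell factor PRDM1 was 2.87-fold higher and BCL6 at least 5.28-fold lower at day 6, while JCHAIN and XBP1 had log2 ratios of 0.13 and 0.43 and IRF4 stayed near day 0. These genes belong to the list being explained and had been seen before, so they are no separate support. Tetracycline and time in culture cannot be told apart from loss of Arp6 here either. The first array with the list lower, at -0.47 on day 2, differed from day 0 in all of them.

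The small difference between micro- and macrochromosome genes was weighed against gene length and scaling. The tables argue against scaling at day 6, where quantile normalization left a difference of -0.0558. Within 20 bins of gene length the difference was -0.0389 (bootstrap SE 0.0115) at day 2 and -0.0458 (0.0146) at day 4, 119% and 78.3% of the differences without bins, but -0.0212 (0.0173) at day 6, 40.9% of it. Gene length may thus account for much of the day 6 difference. With the main filter, differences beyond their bootstrap errors, which hold no error between arrays, were left at days 2 and 4. With no filter on dim probe sets the day 2 difference before any bins was 0.0016. The bootstrap errors are too large to show that gene length matters more at day 6 than at the other days. Chromosome position in the nucleus, which no array measured, and GC content, which was not examined, stay open.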

How the results depend on the processing

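Scaling to the spike-in controls, the floor at the highest unspiked control, matching through synonyms and bounds against each array's background were chosen after seeing the data, and the other alternatives before. Counts are given as higher and lower genes at days 2, 4 and 6, then at all 3 later days, and where a value moved the cause was not tested unless stated. No paired analysis was possible because each day has 1 array.

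The ATF4 list stayed above 0 and the B cell list below 0 under every alternative tried. The ATF4 medians ran from 0.42 to 0.65 at day 2, 0.34 to 1.10 at day 4 and 0.64 to 1.33 at day 6, and the B cell medians from -0.63 to -0.15, -0.92 to -0.31 and -1.65 to -0.79. Of list medians under the alternatives, 585 stayed within their bootstrap error, 215 moved by more, and 13 that lay outside the random range changed sign. Of named genes' mean ratios 962 stayed within the SD between probe sets, 141 moved by more and 0 of those at least 2-fold changed sign, and of array distances 61 stayed within 1.5 times and 5 moved by more.

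With the deposited values unscaled, the lower count at day 2 was 403, the counts were 286 and 740 at day 4, 263 and 1603 at day 6, and 51 and 111 at all 3 days. Ribosomal protein medians were then -0.0796 and -0.20 at days 4 and 6, the glycolysis median -0.10 at day 6, and 2334 genes had an unadjusted trend p under 0.05. This follows from the arrays' different medians. Quantile normalization put the ribosomal protein median at -0.0038 at day 6.

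Without a filter on dim probe sets more genes were tested, with 500 and 423 at day 2, 1084 lower at day 4, 1533 lower at day 6 and 148 lower at all 3 days. The micro minus macro difference was then 0.0016, -0.0881 and -0.11 at the 3 days, the ribosomal protein median -0.12 and -0.0578 at days 4 and 6, and the actin median 0.0302 at day 2. The filter at the 75th percentile tested fewer genes and gave 56 and 21, 142 and 119, 277 and 278, and 35 and 9, a respiratory chain median of 0.0083 at day 4, and 146 genes in the trend at limma's adjusted threshold.

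Without a floor 135 genes were higher at all 3 days. A floor at the 60th percentile, which by construction lowers the ratios of dim genes, gave 77 and 81 at day 2, 250 and 261 at day 4, 405 higher at day 6 and 37 higher at all 3 days, with chromosome class differences of 0.00, -0.0028 and -0.0147. A pseudocount in place of the floor gave 68 and 63, 222 and 195, 351 and 415, and 30 and 12. The floor at the highest unspiked control gave 37 and 36, 125 and 172, 253 and 366, and 20 and 17, with class differences of 0 at all 3 days, which that floor fixes by setting the ratio of any gene below it on both arrays to 0 and which says nothing about dim genes as a source.

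The mean of a gene's probe sets gave 21 lower at all 3 days and Arp6 log2 ratios of -6.49, -6.15 and -6.35. Every probe set by itself, a larger number of items, gave 595 and 648, 1274 and 995, 1799 and 1417, and 258 and 77. The 3-fold threshold gave 31 and 39, 137 and 114, 199 and 273, and 13 and 4, and the 1.5-fold threshold 604 and 759, 1148 and 1110, 1396 and 1456, and 318 and 226.

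Scaling to the spike-in controls gave 1016 and 198 at day 4. The day 4 medians became 0.15 for cohesin and condensin, 0.17 for DNA replication, 0.31 for the respiratory chain and 0.17 for cholesterol synthesis, and the day 6 actin median 0.0193. The median of all tested genes became 0.37 at day 4 and 0.21 at day 6, so these turns follow from a shift common to all genes. With intermediate chromosomes counted as micro the class difference was -0.0419 at day 4 and -0.0348 at day 6. Without day 0 the trend had 765 genes at an unadjusted p under 0.05, without day 2 935, and limma-trend called 604 genes at the adjusted threshold.

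Signal over background limits the dim genes. The highest unspiked control reached 73.3 after scaling, above the floor of 19.4, and of the 89 genes higher at all 3 days, 72 passed that control on at least 1 array. Bounds against each array's background left 155 and 202 genes 2-fold different at day 2, 426 and 319 at day 4, 634 and 482 at day 6, and 69 and 25 at all 3 days.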

Other observations

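The tests in this part were chosen after the main values were seen, and the lists were written before their own medians were computed. Of the tested genes, lists fixed earlier already held 17 of 17 chaperones, 9 of 18 aminoacyl-tRNA synthetases, 0 of 36 plasma cell and secretory genes, 0 of 32 lysosome genes and 0 of 35 signalling genes.

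Genes that carry antigen receptor signals onward held more 2-fold lower than 2-fold higher members at day 6. Of 35 tested adaptors and kinases of B cell receptor and integrin signalling, 10 were at least 2-fold lower and 3 at least 2-fold higher. Over all tested genes 8.35% were lower and 8.48% higher that day, so the higher count was near that share and the lower count above it. The list's medians were -0.05, -0.07 and -0.20 at days 2, 4 and 6, inside the range of random lists. DAPP1, an adaptor downstream of phosphoinositide 3-kinase, was 13.5-fold lower at day 6, the adaptor DOK3 at least 5.33-fold and the GTPase gene RAC2 of blood cells 7.80-fold, while PPP3CA of calcineurin was 7.87-fold higher. The phosphatase CD45 (PTPRC) stood at 0.38 and the adaptor GRB2 at -0.12.

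Aminoacyl-tRNA synthetases of the cytoplasm (18 tested genes) had medians of 0.25, 0.35 and 0.43, and 0 of 10000 random lists reached as high on any day. The 9 that an earlier list held belong to the ATF4 list, so these medians partly repeat its result. The 18 genes were uneven. At day 6 WARS, IARS and GARS, of the ATF4 list, were at 1.75, 1.04 and 1.10, and KARS, DARS and FARSA, outside it, at -0.01, 0.07 and -0.04. Lysosome genes (32) had medians of -0.03, 0.14 and -0.15, inside the range of random lists. Within them CTSS, the cathepsin that trims the invariant chain CD74, was at least 9.17-fold lower at day 6 and TFEB at least 3.57-fold lower, while GLB1 was 2.67-fold higher. Endoplasmic reticulum chaperones (17) had medians of -0.02, -0.19 and 0.28, at the 20.6th, 2.09th and 98.9th percentiles of random lists, so below the random range at day 4 and above it at day 6. Plasma cell and secretory genes (36) had medians of 0.08, 0.16 and 0.31, above the random range at days 4 and 6. These 5 lists were not run under the other scalings.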
